A study of Homo sapiens with 43 samples.

How the data were processed

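The series compared TSA-Seq of nuclear speckles, RNA polymerase II and the nuclear lamina in K562 cells with controls stained without primary antibody. Samples were grouped by target, staining condition and library type from the labels, which gave 27 groups for 43 samples. Condition 1 used the plain staining buffer, Condition 2 added 50% sucrose, and Condition 3 added a reducing agent to the sucrose, per the labels' protocols. Cells were fixed, permeabilised and stained, DNA was purified after reversal of the crosslinks, and libraries were made by ligation and PCR from input and pull-down DNA, per the labels' protocols.

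The values analysed were the authors' deposited classes for SON TSA-Seq under Condition 2, a map of the genome in 10 numbered groups and 1 unranked group. Basecalling and read processing named bcl2fastq 1.8.2, Bowtie2 2.0.2, SAMtools 0.1.19 and build hg19, per the submitters' processing notes, without their parameters. How the score was computed, smoothed and ranked, and whether the 2 pull-downs of the group were pooled, is not given in the sources used here. The labels attach a decile map to the first Condition 2 pull-down and its input and not to its repeat. The map had 9541 segments, 9269 ranked and 272 unranked. All segment starts were multiples of 20 kb, touching segments always differed in class, and each decile covered 283.4 to 283.5 Mb, as tested on the values. The score field held 1000 in every segment and was not used. The unranked length lay mostly in 24 runs of at least 3 Mb, which held 182.84 Mb, and the median unranked run was 60 kb. The classes are ordinal and hold no counts, so depth per sample is unknown and no counting interval of the signal can be given. The direction of the numbering is not given in the sources used here and was taken as rising with the score.

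Equal decile lengths are set by the ranking, so the deposited map can show where high and low ranks lie but not how far apart their signals are. Averages of deciles treat the classes as evenly spaced. Any smoothing of the score before ranking would lengthen segments and make neighbouring ranks alike, which bears on segment lengths and steps.

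Lengths, quartiles and medians were computed for the segments of each decile, with an exact order-statistic interval at 95%. Steps between touching segments were set against 10000 random orders of the segments within each chromosome. Mean deciles were weighted by length. The SD of a chromosome was taken over windows of 10 Mb with at least 5 Mb ranked. Gene counts per chromosome came from the RefSeq annotation of GRCh38.p14, with 59098 genes and 19974 protein-coding genes on the 23 chromosomes, and were divided by the ranked length on hg19. No coordinate of that annotation was used, since its build differs from that of the map. Correlations across chromosomes used 100000 permutations, and the comparison of ends with interiors used 100000 random sign flips over chromosomes. Ends were the outer 5 Mb between the first and the last ranked position. All tests were two-sided unless stated, at a threshold of 0.05. With 1 map, their p describe positions or chromosomes within it and not the spread between samples.

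The tests, alternatives and 25 gene lists were chosen before the data were examined, except where stated. Gene density, gene length, GC content and gene lists by decile had been planned for an annotation and sequence of hg19. Those were not used here, so these 4 results were not computed, and neither were their alternatives. By the rule for named items, the text names the 5 longest segments of decile 10 and of decile 1 and the 3 chromosomes with the highest and the lowest mean decile. Other regions and chromosomes named were chosen after their values were seen. Distances between bins, hills and valleys of the map, distances of decile 10 from deciles 1 and 2, and the flanks of unranked runs, with the change of rank over the 0.2 Mb beside them, were also added after the map was examined. Alternatives were autosomes only, segments at gaps left out, gaps of up to 100 kb bridged, the share in deciles 9 and 10, all annotated genes, each chromosome left out in turn, ends of 2 or 10 Mb and the acrocentric chromosomes left out.

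The procedures were tested on simulated data on the same 23 chromosomes. For ends against interiors, 20 smoothed random maps were made at each size of a rise of the score at the ends. A rise of 0.5 SD gave a mean difference of 1.46 deciles, with 95% of maps called. A rise of 1 SD gave 2.45 deciles and a rise of 2 SD gave 4.08, with 100% called at both, and without a rise 0% were called. Of 20 simulated relations with a correlation of 0.85, 100% were called, and with a correlation of 0, 0% were. These relations were random values for 23 chromosomes and not maps. The simulated maps were given no differences in level between chromosomes, which made up 21.8% of the variance of the real map. The shares called without an effect are therefore not false-call rates for data like these. A random map averaged over 21 bins gave 94.3% of steps of 1 decile, and a random map without averaging 20.3%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.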

Results

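The series used TSA-Seq to rank the genome of K562 cells by nearness to nuclear compartments. In TSA-Seq (tyramide signal amplification sequencing), a peroxidase-coupled antibody deposits biotin on DNA around a stained structure. The biotinylated DNA is then pulled down on streptavidin and sequenced beside its input. K562 is a human chronic myelogenous leukaemia line. The labels describe 43 samples, 21 inputs and 22 pull-downs. Of the pull-downs, 15 were stained with a primary antibody and 7 were controls without one. Antibodies were directed against SON and phosphorylated SC35, both proteins of nuclear speckles, RNA polymerase II, lamin A/C and lamin B. Of the pull-downs with a primary antibody, 6 used the first SON antibody and 1 the second, with 2 each for the other targets. Nuclear speckles are bodies rich in RNA processing factors, and the lamins line the nuclear envelope.

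The values reported here come from 1 map, the ranking of the genome by SON TSA-Seq under Condition 2, in which the staining buffer held 50% sucrose. The group has 2 pull-downs, and the map is taken as 1 measurement with no replicates. It lists 3036.3 Mb of hg19 on chromosomes 1 to 22 and X. Of this length, 2834.56 Mb (93.4%) carried a rank in 10 deciles and 201.741 Mb (6.64%) was left unranked. A decile is an ordinal class without a signal level, and the sequencing depth behind it is unknown. Decile 10 is taken as the highest SON score and decile 1 as the lowest, the usual sense of the number. Were the numbering the other way, every direction below would turn. The signals of the other stains and of the controls without primary antibody were not analysed here, so no background stands beside the ranks.

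The top of the SON ranking was made of fewer and longer domains than the lower deciles. Decile 10 filled 283.46 Mb in 211 segments, with a median length of 700 kb and quartiles of 260 and 1790 kb. Decile 9 had 509 segments with a median of 420 kb, and decile 1 had 629 with a median of 260 kb. Segments were shortest in deciles 2 and 3, where 1362 and 1369 segments had medians of 160 and 140 kb, with the same interval of 140 to 160 kb. Segments over 1 Mb held 83.8% of the length of decile 10, 41.5% of decile 9, 37.4% of decile 1 and at most 16.9% of any other decile.

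The 5 longest decile 10 segments lay on 3 chromosomes. Chromosome 19 held 3 of them, from 45000001 to 56880000 (11.88 Mb), from 8740001 to 19780000 (11.04 Mb) and from 80001 to 7360000 (7.28 Mb). Chromosome 11 held 1 from 60600001 to 69100000 on its long arm, 8.5 Mb in length. Chromosome 17 held 1 from 480001 to 8800000, near the tip of its short arm, 8.32 Mb in length. A segment of chromosome 22, from 36500001 to 43780000, was as long as the shortest of these 5 and was left out by genome order. The 5 longest decile 1 segments were shorter and lay on chromosomes 13, 4 and 6. Chromosome 13 held 2, from 61980001 to 66580000 (4.6 Mb) and from 68540001 to 72680000 (4.14 Mb). On chromosome 4 they ran from 90180001 to 93800000 (3.62 Mb) and from 135100001 to 138420000 (3.32 Mb). On chromosome 6 the segment ran from 101460001 to 104800000 (3.34 Mb). All positions are hg19, and the genes in these segments were not analysed here.

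**Figure D1:**
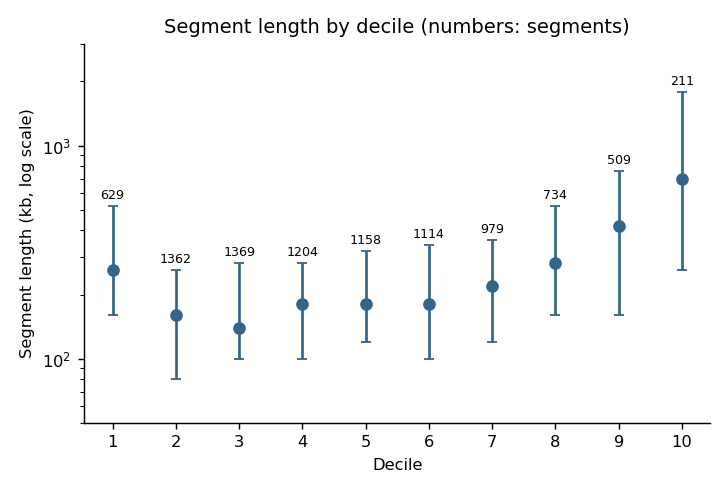
Length of the segments of each SON TSA-Seq decile, in kb on a log scale, with points at the median, bars from the first to the last quartile and the number of segments above each bar. The median rises from 140 kb in decile 3 to 700 kb in decile 10, and decile 1 lies at 260 kb.

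The order-statistic 95% interval of the median was 560 to 960 kb in decile 10, 340 to 460 kb in decile 9, 240 to 280 kb in decile 1 and 140 to 160 kb in deciles 2 and 3. The intervals of deciles 10, 9, 1 and 3 do not overlap, and deciles 2 and 3 are not separated. They treat segments as independent, although neighbouring segments of 1 map are not, and they say nothing of the spread between pull-downs. Because a segment next to an unranked run or a chromosome end is cropped there, 157 of the 211 decile 10 segments have both borders within ranked sequence. Their median was 560 kb. Deciles 10 and 1 are bounded on 1 side only, while a changing score crosses the deciles between, so some excess of length in deciles 10 and 1 follows from the ranking.

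Along the chromosomes the SON rank moved in single steps. All 9014 pairs of touching segments differed by exactly 1 decile, so no decile was skipped between touching segments. Bins 1 Mb apart on a chromosome differed by 1.34 deciles on average and bins 10 Mb apart by 2.78, against 3.30 for random pairs over the whole genome. Those random pairs mostly join different chromosomes, so the gap at 10 Mb holds differences between chromosomes as well as nearness. Regions of decile 10 and of deciles 1 and 2 never lay within 1 Mb of each other. On the chromosomes that carry deciles 1 or 2, the 175 segments of decile 10 lay a median of 9.92 Mb from the nearest, and the closest lay 1.06 Mb away.

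Random orders of the segments within each chromosome gave 23.6% of pairs 1 decile apart on average and 25.6% at most. The two-sided permutation p was 0.0001, the smallest that 10000 orders can give. If the pairs were independent draws, the 0 larger steps in 9014 pairs would allow a share of up to 0.0333%, a limit for counting error only. They are all the touching pairs of the map and share segments, so this limit describes neither this map nor other libraries. Touching segments differ by construction, while random orders also place segments of the same decile side by side, and the test describes this map and not replicate libraries. A simulated random map averaged over 21 bins gave 94.3% of steps of 1 decile. The low p therefore shows only that ranks change smoothly along the chromosome, which smoothing of the score could give by itself.

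Chromosomes 19, 22 and 17 had the highest SON ranks and chromosomes 4, 13 and 18 the lowest. The length-weighted mean decile was 9.43 ± 1.07 (SD, n = 6 windows of 10 Mb) on chromosome 19, 9.10 ± 0.53 (SD, n = 4 windows) on chromosome 22 and 8.72 ± 0.99 (SD, n = 8 windows) on chromosome 17. It was 3.47 ± 1.66 (SD, n = 19 windows) on chromosome 4, 3.78 ± 1.90 (SD, n = 10 windows) on chromosome 13 and 4.36 ± 1.47 (SD, n = 8 windows) on chromosome 18. Chromosomes 19 and 17 are known as gene-dense, and chromosomes 4, 13 and 18 as gene-poor. The mean decile rose with the density of protein-coding genes across the 23 chromosomes.

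On chromosome 19, 70.2% of the ranked length lay in decile 10, against 48.3% on chromosome 22, 43.2% on chromosome 17 and 29.9% on chromosome 16. Chromosomes 19, 22 and 17 together made up 5.94% of the ranked length and held 31.6% of decile 10 and none of decile 1. Decile 1 was also missing from chromosomes 15, 16 and 20. At the other end, 29.6% of chromosome 4 and 26.2% of chromosome 13 lay in decile 1. Chromosomes 4, 13 and 18 made up 12.6% of the ranked length and held 33.0% of decile 1 and 1.19% of decile 10. Chromosome 18 reached decile 9 and had no decile 10. The decile 10 of chromosome 4 lay near the tip of its short arm, from 400001 to 1420000 and from 1480001 to 3520000. That of chromosome 13 was 1 segment of 0.32 Mb at the end of the long arm, from 114740001 to 115060000. The X chromosome, at a mean of 5.06 ± 1.96 (SD, n = 16 windows), had 4.76% of its length in decile 10 and 4.45% in decile 1.

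**Figure D2:**
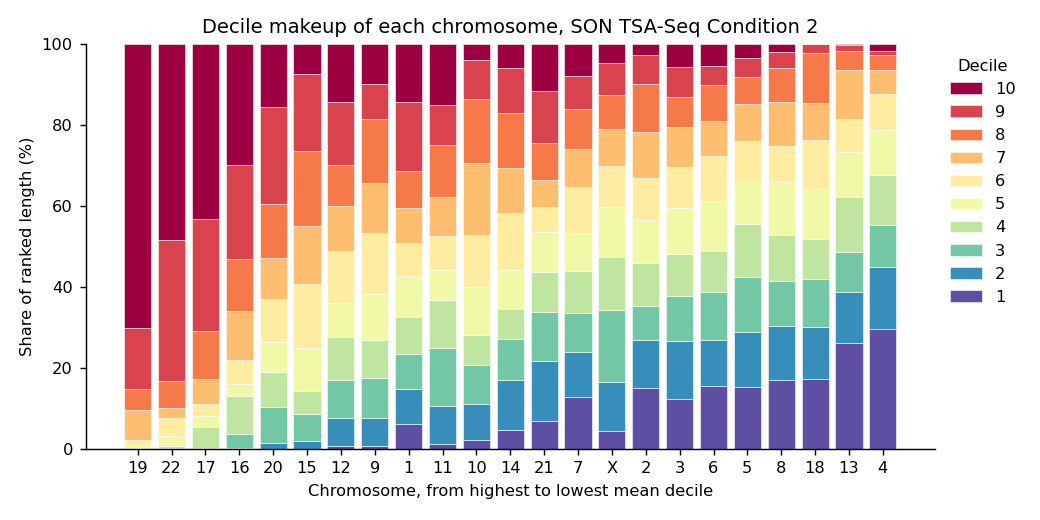
Share of the ranked length of each chromosome, in percent, in each SON TSA-Seq decile, with chromosomes ordered from the highest to the lowest mean decile. Decile 10 covers 70.2% of chromosome 19, and decile 1 covers 29.6% of chromosome 4.

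**Figure D3:**
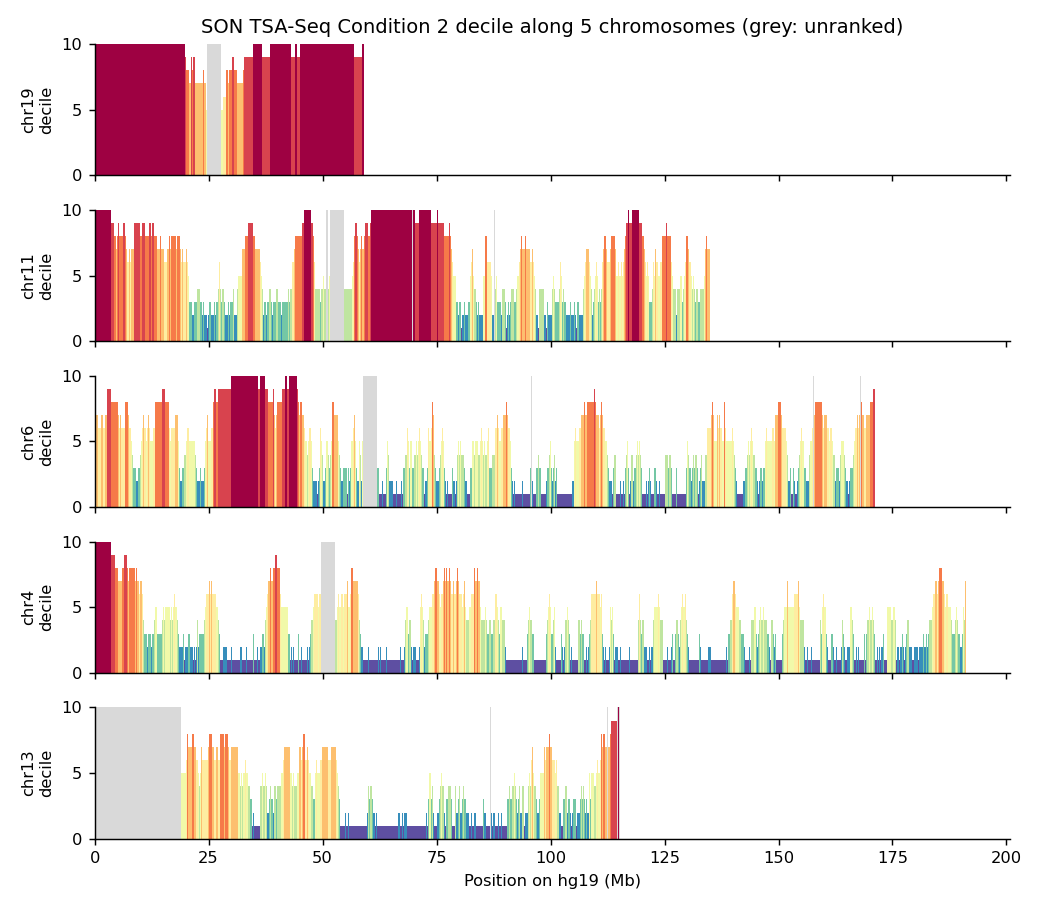
SON TSA-Seq decile along chromosomes 19, 11, 6, 4 and 13, with the hg19 position in Mb on the horizontal axis, the decile on the vertical axis and unranked runs in grey. Chromosome 19 is mostly decile 10, chromosomes 4 and 13 are low over most of their length, and the decile 10 of chromosome 4 lies near 1 tip.

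Pearson's r between mean decile and protein-coding genes per Mb was 0.859 and Spearman's rho 0.934 (n = 23 chromosomes). Both two-sided permutation p were 1e-05, the smallest that 100000 resamples can give, and both were 1.5e-05 after Benjamini-Hochberg adjustment over 6 relations. Chromosome 19 had 26.0 genes per Mb, chromosome 17 had 15.0 and chromosome 22 had 12.9, against 4.10 on chromosome 4, 3.62 on chromosome 18 and 3.54 on chromosome 13. Without chromosomes 19 and 17, the farthest from the median density, r was 0.922 and rho 0.914 (n = 21). Densities of all genes, long non-coding RNA genes, pseudogenes and microRNA genes gave r of 0.917, 0.731, 0.884 and 0.831 and rho of 0.909, 0.755, 0.854 and 0.848. The adjusted permutation p of these 4 relations were at most 3.6e-05 for r and 7.2e-05 for rho. Without the chromosomes farthest from each median, r was 0.900, 0.785, 0.813 and 0.829. Longer chromosomes ranked lower, with r of -0.573 (permutation p = 0.0043, adjusted 0.0043) and rho of -0.561 (permutation p = 0.0062, adjusted 0.0062). Without chromosomes 2 and 22, r with length was -0.504 (permutation p = 0.020, n = 21). Chromosomes are parts of 1 map and not replicates, and gene counts were those of GRCh38.p14 over lengths ranked on hg19. Differences between chromosomes made up 21.8% of the variance of the decile over the ranked genome, so most of the spread lay within chromosomes.

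**Figure D4:**
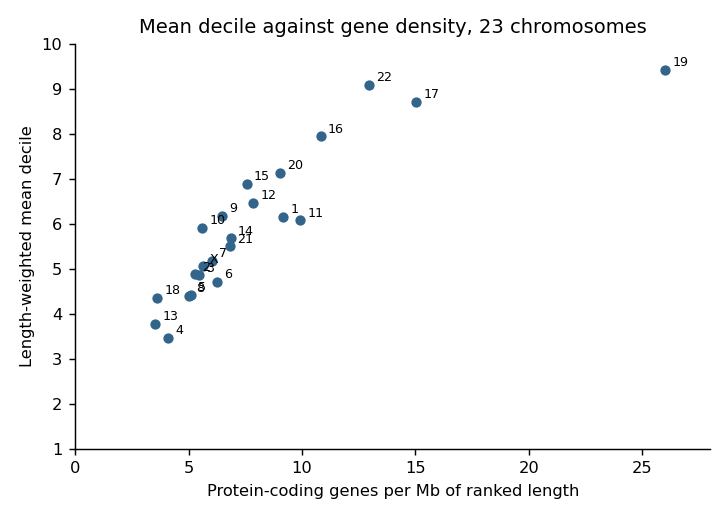
Length-weighted mean SON TSA-Seq decile of each of 23 chromosomes against its protein-coding genes per Mb of ranked length, 1 point per chromosome. The points rise together (rho 0.934), and chromosome 19 lies far to the right at 26.0 genes per Mb.

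Chromosome ends ranked above chromosome interiors. The outer 5 Mb of the map had a mean decile of 7.90 ± 1.24 (SD, n = 23 chromosomes) and the interior 5.74 ± 1.71 (SD, n = 23). The ends were higher by 2.16 ± 1.39 deciles (SD, n = 23) and on 21 of 23 chromosomes. By the mean of both ends, the exceptions were chromosome 15, with a difference of -1.42, and chromosome 22, with -0.37. On chromosome 15 both the first 5 Mb, at 5.33, and the last, at 5.88, lay below the interior at 7.05. Single ends also lay below the interior on chromosomes where the mean of both ends was higher. These were the first 5 Mb of chromosomes 2, 3 and 9 and the last 5 Mb of chromosomes 1 and 11. Their distance from the interior ranged from 6.00 against 6.09 on chromosome 1 to 3.43 against 4.79 on chromosome 3. Chromosomes 15 and 22 are acrocentric, but so are chromosomes 13, 14 and 21, where the ends were higher by 3.38, 3.45 and 3.91 deciles. On these 5 chromosomes the map begins after a long unranked run, so its start is no telomere.

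The start of chromosome 16 lay wholly in decile 10. The start of chromosome 19, both ends of chromosome 17 and the end of chromosome 5 had means of 9.996, 9.95, 9.99 and 9.95. Of the 46 ends, 19 had a mean of at least 9 and 4 a mean below 5. The lowest were the start of chromosome 3 at 3.43, the end of chromosome 4 at 4.36, the start of chromosome 2 at 4.50 and the start of chromosome 8 at 4.86. Ends of the same chromosome differed widely on chromosome 4, from 9.49 at the start to 4.36 at the end, and on chromosome 3, from 3.43 to 8.49. On chromosome 5, with an interior at 4.20, the ends exceeded the interior by 3.99 deciles.

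**Figure D5:**
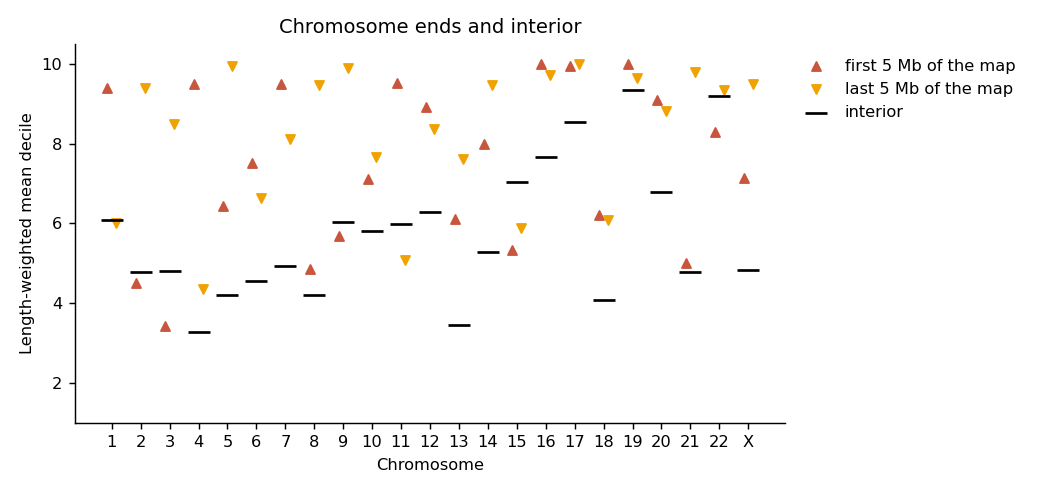
Length-weighted mean SON TSA-Seq decile of the first 5 Mb and the last 5 Mb of the map of each chromosome (triangles) and of the interior between them (bars). The mean of both ends lies above the interior on 21 of 23 chromosomes, and single ends range from 3.43 to 10.

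The sign-flip permutation p of the difference was 1e-05 (two-sided), the smallest that 100000 resamples can give. The difference was 1.43 ± 1.17 (SD, n = 23) when the outer 10 Mb counted as the end, with ends higher on 22 of 23 chromosomes (sign-flip permutation p = 3e-05). As for the other comparisons, the spread is between chromosomes of 1 map and not between pull-downs.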

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

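The alternatives without the 2 chromosomes farthest from the median gene density and without the outermost 1 Mb of each end were chosen after seeing the data. Of 70 alternatives, most left out 1 chromosome at a time from the relation with gene density, so they are not independent checks. In total, 68 of the 70 kept the direction and call or stayed within the interval of the value. The other 2 moved by construction: on autosomes only, decile 10 covered 10.30% and decile 1 10.31% of the ranked length, because the X chromosome holds less of both. The median decile 10 segment was 560 kb without segments at gaps, at the lower limit of its interval of 560 to 960 kb, and 780 kb on autosomes. When gaps of up to 100 kb were bridged, 98.5% of 9190 steps were of 1 decile. The other 142 pairs lay in the same decile, and 0 were more than 1 decile apart. Leaving out each chromosome in turn gave r with gene density from 0.842 without chromosome 17 to 0.928 without chromosome 19, and rho from 0.924 to 0.946. With the share in deciles 9 and 10 in place of the mean, r was 0.901 and rho 0.972. Chromosome ends exceeded the interior by 2.35 deciles at 2 Mb, 1.43 at 10 Mb, 2.26 without acrocentric chromosomes (higher on 18 of 18) and 2.05 without the outermost 1 Mb. No paired analysis was possible because the values are 1 map with no replicate columns. Depth is unknown, so its effect on the ranks cannot be assessed. The alternatives for results by gene position or GC content were not run.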

Other observations

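All tests in this part were chosen only after the map and the patterns they address had been seen, including that without the outermost 1 Mb of each end. So were the summaries of hills, valleys and flanks.

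Between its extremes the SON map was made of many small rises and dips. Counting only segments with ranked neighbours on both sides, it held 2125 local hills, 157 of them in decile 10 and 1968 below it, and 2188 local valleys, 625 of them in decile 1. The count leaves out decile 10 segments beside an unranked run or a chromosome end, since 157 of 211 had both neighbours ranked. Every counted segment of decile 10 is a hill, and every one of decile 1 a valley, by construction. Of 4158 moves between a hill and a valley, 2156 crossed 1 decile. With 1 map and unknown depth, such small moves cannot be told from noise at the border of 2 classes. Of the 4158 moves, 3 crossed all deciles from 1 to 10 or back without a turn, on 2 chromosomes. On chromosome 7 the rank rose from decile 1 to decile 10 over the 1760 kb from 126600001 to 128360000 and fell from decile 10 to decile 1 over the 2360 kb from 6680001 to 9040000. On chromosome 1 it rose over the 2120 kb from 199720001 to 201840000. These stretches (hg19) were picked for their values and are places where the highest and the lowest SON ranks lie close together.

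Sequence beside the longest unranked run of each chromosome, which on most chromosomes spans the centromere, showed no difference from the rest beyond the spread between chromosomes. On the 18 chromosomes with ranked sequence on both sides, the 5 Mb on each side had a mean difference of -0.06 ± 1.53 deciles (SD, n = 18, sign-flip permutation p = 0.87), with 9 chromosomes higher and 9 lower. With the other 5 chromosomes, ranked on 1 side of the run, it was 0.03 ± 1.59 (SD, n = 23, sign-flip permutation p = 0.93), with 11 higher and 12 lower. Chromosome 2 was higher there by 2.97 deciles, while chromosome 3 had a difference of -2.78 and chromosome 19 of -2.39.

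Ranks beside long unranked runs were alike on both sides, and low ranks rose toward them. Across the 19 runs of at least 3 Mb with ranked sequence on both sides, 17 pairs of flanking bins (89.4737%) lay within 1 decile, against 43.4% expected for bins as far apart (one-sided exact p = 3.74e-05). Over the last 0.2 Mb, the 11 sides in deciles 1 to 3 rose by 3 ± 1 deciles (SD), against 0.09 expected. The 22 sides in deciles 4 to 7 rose by 1.18 ± 1.01 (SD), from a mean of 5.00 to 6.18, against -0.06 expected. The 1 side in deciles 8 to 10 changed by -1, against -0.14 expected. Expected changes are means over ranked stretches of 0.2 Mb that start in the same decile. Two-sided resampling of such stretches, with sides taken as independent, gave p of 1e-05, 1e-05 and 0.41. At runs over 100 kb and under 3 Mb, the changes were 3.14 ± 0.69 (SD, 7 sides), 0.75 ± 0.84 (SD, 36 sides, from a mean of 5.53 to 6.28) and -0.58 ± 0.51 (SD, 12 sides), with resampling p of 1e-05, 1e-05 and 0.0079. A pull toward middle ranks beside unranked runs, smoothing across joined bins and like ranks on both sides of the centromere are candidate explanations. If the run were removed, 100% of flanking pairs would be expected within 1 decile, but 2 of the 19 lay farther apart. This argues against smoothing across joined bins at those 2 runs. For the likeness of the sides in the other 17 pairs, the candidates cannot be told apart here. The 4 pairs that changed between the run and 1 Mb away are too few for an exact McNemar test to go below 0.125. Smoothing across joined bins would raise a side only toward a higher other side, and like ranks alone give no rise. At the long runs, 11 of 11 sides in deciles 1 to 3 and 15 of 22 in deciles 4 to 7 rose, and 0 fell. This argues against both as the source of the rise. A general rise stays open at the long runs, where 1 high side cannot show whether high ranks fall. At the shorter runs 7 of 12 high sides fell, with a mean change of -0.58 against -0.11 expected, which argues against a general rise there. That 0 rose says less, since a side in decile 10 cannot rise.

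Farther from these runs, on both sides at once, pairs within 1 decile numbered 13 of 19 at 0.1 Mb, 6 of 14 at 0.25 Mb, 10 of 16 at 0.5 Mb, 13 of 17 (76.4706%) at 1 Mb and 10 of 16 at 2 Mb, so the runs counted differ between distances. The share expected for bins as far apart was 43.0%, 43.6%, 41.4%, 39.0% and 36.9% (one-sided exact p = 0.022, 0.62, 0.073, 0.0019 and 0.033), and that expected if the run were removed was 91.5%, 77.3%, 63.1%, 50.8% and 42.9%. Across runs over 100 kb and under 3 Mb, 36 of 37 pairs of flanking bins lay within 1 decile, against 93.3% expected for bins as far apart (one-sided exact p = 0.27).

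The rise of the chromosome mean with gene density was tested against 2 other properties of chromosomes. With ranked length held fixed the partial r was 0.826387 (permutation p = 1e-05), which argues against chromosome length as the whole cause. With the mean decile taken over interiors alone, and gene density still that of the whole chromosome, r was 0.852977 (permutation p = 1e-05). This argues against raised ranks at the ends as the source of the relation. It is a weak test, because the interior makes up most of a chromosome and its mean lies close to the chromosome mean. Genes at the ends were not separated from the density. No biological explanation was tested, since the signals of the other stains and of the controls, and whether SON rank follows genes within chromosomes, were not analysed here. That SON rank follows gene density remains a hypothesis drawn from 1 map.

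The higher rank of chromosome ends was tested against an edge effect of smoothing and against a few gene-dense chromosomes. Without the outermost 1 Mb the ends still exceeded the interior by 2.04947 deciles (sign-flip permutation p = 1e-05, higher on 21 of 23 chromosomes), which argues against an edge effect within that distance. On the 11 chromosomes under the median gene density the difference was 2.80087 ± 0.968 (SD, n = 11, sign-flip permutation p = 0.001), higher on 11 of 11, which argues against gene-dense chromosomes as the only source. A higher density of genes at the ends themselves stays open, since gene positions on hg19 were not used here, and no biological explanation was tested.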
